A study of Mus musculus with 3 samples.

How the data were processed

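Cultured lymph node stromal cells of BALB/c mice, the fibroblast-like and vascular cells that form the scaffold of a lymph node, were transfected with 400 pmol of control siRNA or of siRNA against Eif4g3, per the labels' protocols. Medium was changed at 24 h and cells were harvested at 48 h. Cells of 7 plates per siRNA were pooled, lysed and run on a continuous 10% to 60% sucrose gradient, which separates mRNAs by how many ribosomes they carry. Gradient fractions were pooled into top, light polysome and heavy polysome RNA, and 200 ng of total RNA was labelled per sample. Each of the 3 fractions was hybridised to 1 Agilent 2-colour array, with Eif4g3 siRNA RNA in Cy5 and control siRNA RNA in Cy3 on all 3 arrays and no dye swap. There was 1 array per fraction, so no replicate error exists and no p-value across genes was computed.

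The deposited scanner files hold a linear intensity per spot and channel, written by Agilent Feature Extraction 10.5.1.1, per the file headers. They also hold the software's own log10 ratio of red over green processed signal with its error, per the file headers, and a p-value of that ratio from the software's error model for single spots, per the file headers. Flags for spots well above background, saturated or non-uniform come from the same deposited files. The authors' deposited value table holds log2 ratios, which equalled the software's log10 ratio turned to log2, with a largest difference of 3.5e-06. Its scale and direction were thereby settled, and its column medians were -0.09 for the top, -0.01 for the light and 0.22 for the heavy array. Centring beyond the software's dye normalization is not given in the sources used here. Probe coordinates in the files are on the mm8 build (NCBI build 36).

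Ratios were computed anew from the mean signals and median local backgrounds with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0. The offset pulls ratios of dim spots towards 0. Per array the slope of these ratios on the software's ratios was 0.571 for the top, 0.718 for the light and 0.721 for the heavy array, so ratios on the top array are the most compressed. Spots of 1 probe were averaged after spots with outlier marks were left out, which numbered 220, 170 and 183 on the top, light and heavy arrays. No spot was saturated. A probe counted as measured when it was well above background in both channels. Genes follow the files' gene names, and a gene's value is the mean over its measured probes. The difference of heavy minus top used the probes measured on both arrays. Of 27745 gene names, 19942 matched a current symbol in a GRCm38 reference table, used for names only. Clone or predicted names, some of them among the matched ones, numbered 11630 and were counted and never named.

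A gene was called higher or lower at 2-fold, a log2 ratio of 1 or -1. The error given beside a value is the software's error of the log ratio, combined over the gene's probes, which covers the spot and not biological replication. It was computed for the software's own ratio and was not rescaled to the more compressed ratios given here. For 10 repeated spots per probe, the median SD of the log2 ratio was 0.06 on the top, 0.06 on the light and 0.09 on the heavy array. Between different probes of a gene the median SD was 0.11, 0.16 and 0.15. For each of 21 gene lists, the median was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and a percentile at or beyond 2.5 or 97.5 is stated as outside the range of random lists. These percentiles describe these arrays. Lists with fewer than 5 measured members have values only.

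The gene lists, the threshold, the alternatives and the rule for named genes were set before the data were examined. Named were Eif4g1, Eif4g2, Eif4g3, Deaf1 and Anpep, then the 12 highest and 12 lowest genes of heavy minus top, the 10 highest and 10 lowest of the heavy array and the 6 highest and 6 lowest of the top and the light array. These had to pass 2-fold, be measured on all 3 arrays with at least median signal, and have all measured probes on the same side of 0. A gene with 1 measured probe meets the last condition by itself, as many of the genes named below do, so naming does not mean that probes agreed. From each list the 2 highest and 2 lowest members by heavy minus top were eligible for naming. For genes with a signal in 1 channel alone, a bound was computed after Aquantile normalization between arrays, as the bright channel over the higher of the dim probe's signal and the lowest signal well above background, which is open to dye bias. The control channel's heavy over top signal was taken on the same scale.

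The steps were tested on simulated data. With the control signals of each array, an added dye trend and noise, 46% of 100 probes changed 3-fold were called on a simulated top array of 15396 probes, 75% of 100 on a simulated light array of 21987 and 93% of 100 on a simulated heavy array of 22645. Of 100 probes changed 1.5-fold, 0%, 1% and 0% were called, and 0 unchanged probes were called on any of the arrays. That 0 was largely fixed in advance, since the simulated noise was narrower than the spread of the real ratios. Their SD was 0.28 on the top, 0.30 on the light and 0.32 on the heavy array. Differences between lysates and gene-specific dye bias were not simulated, so the simulation gives no rate of false calls on the real arrays. The list step, run on 10000 simulated genes, placed 2 of 100 unchanged lists of 30 genes outside the range of random lists. It placed 12 of 20 lists shifted by 0.25 and 20 of 20 shifted by 0.5 above that range. Simulated genes varied independently, so the small share of unchanged lists outside was largely fixed in advance. Genes of a real list can vary together, so this gives no rate of false placements on the real arrays. Alternatives were another or no background correction, the software's ratio, the deposited value table, no loess, other filters and probe rules, other thresholds and another pair of fractions. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.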

Results

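Polysome fractions of cultured mouse lymph node stromal cells treated with Eif4g3 siRNA were compared with those of cells treated with control siRNA. Eif4g3 encodes eIF4GII, a scaffold protein of the complex that brings ribosomes to capped mRNAs. The top fraction of the gradient holds free and lightly loaded mRNA, and the light and heavy polysome fractions hold mRNAs with few and with many ribosomes. Each fraction was 1 array with both siRNAs, without replicates, so array and fraction cannot be told apart. Of 41174 probes, 14338 (34.8%) were measured in both channels in the top fraction, 20658 (50.2%) in the light and 21245 (51.6%) in the heavy polysome fraction. These covered 10943, 14094 and 14402 genes, of which 10639 were measured on all 3 arrays. The top array was the dimmest, with an upper-quartile signal of 67.2 in the control and 78.3 in the siRNA channel, against 313 and 725 for the light and 1100 and 407 for the heavy array. The channel gaps of the light and heavy arrays thus ran in opposite directions before normalization.

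The siRNA target was lower on all 3 arrays. The log2 ratio of Eif4g3 siRNA over control siRNA for Eif4g3 was -0.43 ± 0.16 (spot error) in the top fraction, -1.06 ± 0.16 in the light and -1.77 ± 0.19 in the heavy polysome fraction. The fall passed 2-fold in the light and heavy fractions, where it was 2.09-fold and 3.41-fold, though without loess the light value was -0.89, short of 2-fold. Eif4g3 has 2 probes near its 3' end on the plus strand of chromosome 4, from 137475547 to 137478087 and from 137478284 to 137478343 (mm8). In the heavy fraction they gave -1.67 ± 0.26 and -1.87 ± 0.26. The heavy minus top difference was -1.34 ± 0.25, and -0.99 with the scanner software's ratio, which falls short of 2-fold. The related Eif4g1, which encodes eIF4GI, had -0.04 ± 0.25 in the top, 0.15 ± 0.15 in the light and -0.38 ± 0.15 in the heavy fraction, and its 2 probes differed there (-0.78 and 0.02). Eif4g2, which encodes a related protein lacking the eIF4E binding site, had -0.28 ± 0.11, -0.50 ± 0.11 and -0.31 ± 0.10. Deaf1, a transcriptional regulator of tissue antigens in stromal cells, had 0.15 ± 0.23, -0.15 ± 0.18 and -0.13 ± 0.15. Anpep, an aminopeptidase of the cell surface, had -0.01 ± 0.25, -0.27 ± 0.21 and -0.66 ± 0.21. None of these 4 passed 2-fold on an array.

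**Figure D1:**
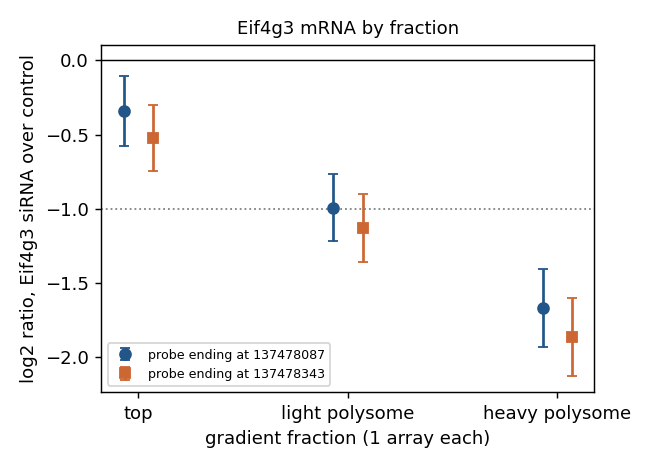
Log2 ratio of Eif4g3 siRNA over control siRNA (y axis) for the 2 Eif4g3 probes in each gradient fraction (x axis, 1 array each). Bars are the spot errors, the dotted line marks 2-fold, and both probes sit lowest in the heavy fraction, at -1.67 and -1.87.

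In the heavy polysome fraction, genes of the interferon response were higher and matrix and glycolysis genes lower after Eif4g3 siRNA. Of 14402 measured genes, 73 were higher and 44 lower at 2-fold. The highest named gene was the interferon-induced Ifi27, now named Ifi27l2a (1.72 ± 0.15). The interferon-induced Rtp4 (1.48 ± 0.26) and Bst2, which tethers budding viruses (1.24 ± 0.23), also rose. The interferon-stimulated list had a median of 0.66 over 37 measured genes, above all 10000 random lists, with 10 members at 2-fold or more, including the ubiquitin-like modifier gene Isg15 (1.32). Other genes that rose were Ccng2, a cyclin of growth arrest (1.498 ± 0.253), Ywhah, a 14-3-3 protein (1.44 ± 0.24), Trappc2, of vesicle traffic (1.43 ± 0.25), Nppb, a natriuretic peptide (1.41 ± 0.17), Egr1, an immediate early transcription factor (1.40 ± 0.24), Rmrp, a noncoding RNA (1.40 ± 0.26), and Aldh1a3, of retinoic acid synthesis (1.19 ± 0.23). In control cells Rmrp had far less signal in the heavy than in the top fraction (log2 -6.66, relative to each array's signal distribution).

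Bcap29, which encodes a membrane protein of the endoplasmic reticulum, was the lowest named gene in the heavy fraction (-2.19 ± 0.29), below Eif4g3. Lmnb1 (lamin B1, -1.66 ± 0.26), Ddit4, an inhibitor of mTOR signalling (-1.47 ± 0.24), and the glycolytic enzyme gene Eno1 (-1.43 ± 0.24) also fell. So did Cndp2 (-1.30 ± 0.23), the plasminogen activator gene Plat (-1.26 ± 0.17), Dnajc1 (-1.24 ± 0.14), Copb1 of the vesicle coat (-1.24 ± 0.24) and the chaperone gene Canx (-1.13 ± 0.13). Extracellular matrix genes had a median of -0.43, with 35 of 41 below 0 and 0 past 2-fold, below all random lists. The value of Bgn was -0.94. Glycolysis and hypoxia genes had a median of -0.26 (24 of 31 below 0, percentile 0), endoplasmic reticulum chaperones -0.25 (22 of 30, percentile 0) and stress response genes -0.23 (23 of 33, percentile 0.02), or -0.145 without the aminoacyl-tRNA synthetase genes of that list (percentile 1.9). Sterol genes had a median of -0.21 (percentile 0.37), proteasome genes -0.19 (percentile 0.15) and cytokine genes -0.15 (percentile 0.91), the last within the range of random lists under 6 of the 8 alternatives. Ribosomal protein genes had a median of 0.30 (71 of 80 above 0), where 95% of random lists lay between 0.033 and 0.215. Oxidative phosphorylation genes had 0.20 (58 of 77 above 0, percentile 99.4), and 0 members of either list were past 2-fold. With no loess the counts rose to 202 higher and 124 lower, and with the software's ratio to 252 and 103.

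In the top fraction, which holds mRNA outside polysomes, ribosomal protein mRNAs were higher and oxidative phosphorylation mRNAs lower after Eif4g3 siRNA. Ribosomal protein genes had a median of 0.53, with 78 of 80 above 0 and 9 past 2-fold, above all random lists. Rpsa (1.69 ± 0.19) and Rplp1 (1.34 ± 0.21) were among the 6 highest named genes. The others were Arpc1b (2.65 ± 0.30) and Arpc1a (1.38 ± 0.25), which encode subunits of the actin-nucleating Arp2/3 complex, the neuronal immediate early gene Arc (1.59 ± 0.26) and Anapc5 of the anaphase-promoting complex (1.46 ± 0.17). Elongation factor and other TOP mRNAs, which share a 5' terminal pyrimidine tract with ribosomal protein mRNAs, had a median of 0.43 (11 of 13 above 0, percentile 99.96). Initiation factor genes had 0.11 (percentile 99.87). Oxidative phosphorylation genes had a median of -0.35, with 73 of 77 below 0 and 2 past 2-fold. Endoplasmic reticulum chaperones had -0.28 (percentile 0.01). Interferon-stimulated genes had 0.44, with 26 of 27 above 0, a median inside the range of random lists when restricted to bright probes (0.24, percentile 95.8). Genes that fell included Spp1, osteopontin (-1.58 ± 0.26), the lysosomal protease gene Ctsl (-1.55 ± 0.25), Hmgn3 (-1.34 ± 0.25), Ctla2a (-1.29 ± 0.24), Rheb, an activator of mTOR (-1.20 ± 0.23), and the chemokine gene Ccl2 (-1.20 ± 0.23). Of 10943 measured genes, 47 were higher and 29 lower at 2-fold, against 151 and 146 with the software's ratio, so that 50.8% in place of 61.8% of the calls were higher.

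In the light polysome fraction, interferon-stimulated genes had the highest median of the lists, 0.74 over 36 genes with 10 past 2-fold. Ywhah (1.61 ± 0.25), Aldh1a3 (1.52 ± 0.25), Rtp4 (1.51 ± 0.25), the transcription factor gene Zbtb20 (1.51 ± 0.18), the fibrillin gene Fbn1 (1.49 ± 0.18) and Fhl1 (1.44 ± 0.24) were the highest named genes. The lowest were Bcap29 (-1.92 ± 0.28), Hmgn3 (-1.44 ± 0.21), the nucleotide sugar transporter gene Slc35d1 (-1.27 ± 0.24), C1qtnf6 (-1.24 ± 0.23), Figf, a vascular growth factor now named Vegfd (-1.23 ± 0.23), and Ctla2a (-1.13 ± 0.23). Extracellular matrix genes had a median of 0.17 (percentile 99.91), cell cycle genes 0.20 (percentile 99.98) and ribosomal protein genes 0.10 (percentile 99.48). Markers of epithelial, smooth muscle and pericyte cells had 0.36 over 9 measured genes (percentile 99.86), and were within the range of random lists without loess (0.02) or without the background filter (0.05). Of 14094 measured genes, 56 were higher and 41 lower at 2-fold. Without loess 153 were higher, so that 84.5% in place of 57.7% of calls were higher.

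Across genes, which are not independent replicates, ratios of the heavy and light fractions had Pearson's r = 0.45 (rho 0.37) over 13695 genes, those of the light and top fractions 0.37 (rho 0.34) over 10701, and those of the heavy and top fractions 0.24 (rho 0.20) over 10731. Without loess r of heavy and light was -0.06. Light and heavy calls shared 26 higher genes, where independent lists would share 0.30, and 9 lower ones (0.13). Top and heavy shared 4 higher (0.28) and 3 lower (0.09). The arrays share the lysate pools and the dye order, which can give shared calls by themselves, so independence is not the value expected without an effect of the fractions. On all 3 arrays 3 genes were higher, of which 2 have gene names, Egr1 and the phosphatase gene Dusp2, and 2 were lower, Bcap29 and Spp1; Dusp2 was chosen after its values were seen. Among genes with a signal in 1 channel alone, 3 had a bound of at least 2-fold, all higher in the heavy fraction. The named one, Epb4.2, an erythrocyte membrane protein gene, was at least 3.13-fold higher after Eif4g3 siRNA. In the heavy fraction 83 genes had a signal in the siRNA channel alone and 1257 in the control channel alone. The siRNA channel was the dimmer one there, with an upper-quartile signal of 407 against 1100. Genes lower after siRNA could thus more readily drop out of the measured ones, and these bounds give no direction for such genes.

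The difference between the heavy and the top ratio addresses whether an mRNA's place in the gradient, relative to other mRNAs, differed after Eif4g3 siRNA. A dye bias common to both arrays cancels in it only in part, since ratios on the top array are more compressed. Loess set the median ratio of measured genes near 0 (0.002 top, 0.015 light, -0.014 heavy). A shift of all mRNAs between fractions therefore cannot be seen in these ratios. Oxidative phosphorylation mRNAs had higher ratios in the heavy than in the top fraction. Their median difference was 0.54, with 69 of 77 above 0 and 14 at 2-fold or more, above all random lists. In the light fraction their median ratio was -0.03, within the range of random lists (percentile 30.8). Ndufa1 of complex I (1.40 ± 0.21), Cox6a1 of complex IV (1.38 ± 0.30) and Atp5g3 of the ATP synthase (1.31 ± 0.30) were among the 12 highest named genes. Sdha was the lowest of the list (-0.88 ± 0.38). The remaining highest genes were the chemokine genes Ccl8 (1.71 ± 0.31) and Cklf (1.48 ± 0.31), Snrpd3 of the spliceosome (1.61 ± 0.22), Nppb (1.48 ± 0.23), the matrix protein gene Mgp (1.46 ± 0.30), Ctsl (1.36 ± 0.32), the thioredoxin gene Txn1 (1.35 ± 0.30), Zcd1, a mitochondrial outer membrane protein gene now named Cisd1 (1.34 ± 0.30), and Rheb (1.29 ± 0.31).

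Translation factor, glycolysis and matrix mRNAs had lower ratios in the heavy than in the top fraction. Initiation factors had a median difference of -0.25 (35 of 50 below 0, percentile 0), with Eif4g3 and the poly(A) binding protein gene Pabpc1 (-1.20 ± 0.30) past 2-fold. Elongation factor and TOP mRNAs had -0.44 (percentile 0.09), with Eef2 (-1.27 ± 0.18) and Eef1a1 (-1.01 ± 0.21) past 2-fold, and ribosomal proteins -0.22 (62 of 80 below 0, 5 past 2-fold, percentile 0.01). Rpsa had -1.68 ± 0.24 and Rpl4 -1.19 ± 0.30. Glycolysis and hypoxia genes had -0.43 (21 of 28 below 0, percentile 0) with 3 past 2-fold, among them Eno1 (-1.81 ± 0.32) and Pfkl (-1.06 ± 0.30). Extracellular matrix genes had -0.36 (28 of 38 below 0, percentile 0), with Bgn, biglycan, at -1.03 ± 0.30. The highest members of these lists were Eif4e3 (0.53 ± 0.32) of the initiation factors, Btf3 (0.19 ± 0.21) of the TOP mRNAs and Rps27l (0.896 ± 0.295) of the ribosomal proteins. For glycolysis and matrix genes they were Bnip3 (0.42 ± 0.31) and Timp1 (0.83 ± 0.21). Other genes among the 12 lowest were Arpc1a (-1.90 ± 0.32), Arpc1b (-1.84 ± 0.36), Lmnb1 (-1.79 ± 0.33), Ddit4 (-1.40 ± 0.32), the dynactin gene Dctn1 (-1.34 ± 0.33), the myosin gene Myh9 (-1.30 ± 0.30), the chaperone gene Hspa8 (-1.30 ± 0.21) and Ftl2, a ferritin light chain copy that its probe may not tell from the main gene (-1.23 ± 0.30).

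Sterol genes (-0.24, percentile 0.1) and cell cycle genes (-0.18, 30 of 47 below 0, percentile 0.26) were also below the range of random lists. Cell cycle members ran from Mcm7 (-1.23 ± 0.30) to Cenpa (0.80 ± 0.30). The cell cycle list was within the range of random lists without the background filter (-0.09, percentile 6.65). Proteasome (-0.17, percentile 0.96), stress response (-0.16, percentile 1.78), mRNA decay (-0.19, percentile 1.86) and internal entry or eIF4E-sensitive genes (-0.17, percentile 2.03) were below it too, each within it under 3 or 4 of the 8 alternatives. The stress response value rested on 6 aminoacyl-tRNA synthetase genes. Without them, a choice made after seeing the data, the median was 0.010 over 24 genes (13 above 0, percentile 39.2). Interferon-stimulated genes had 0.28 (percentile 99.99), but -0.15 with an offset of 0 and -0.20 with the software's ratio, so the direction of their difference was not settled. Lists within the range of random lists were antigen presentation genes (0.13), with B2m at 1.28 ± 0.21, endoplasmic reticulum chaperones (0.02), fibroblastic stromal markers (-0.05) and cytokines (-0.04). So were leukocyte markers (-0.07 over 6 genes) and epithelial, smooth muscle and pericyte markers (-0.30 over 7 genes). Endothelial markers had -0.13 over 4 measured genes, and 3 measured peripheral antigen genes had -0.21, with Ptprn, an autoantigen of diabetes, at -1.20 ± 0.41. Of 10721 genes measured on both arrays, 87 had a higher and 75 a lower ratio in heavy than in top at 2-fold. The software's ratio gave 301 and 155, which raised the share of higher calls from 53.7% to 66.0%, and no loess lowered it to 37.0%.

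**Figure D2:**
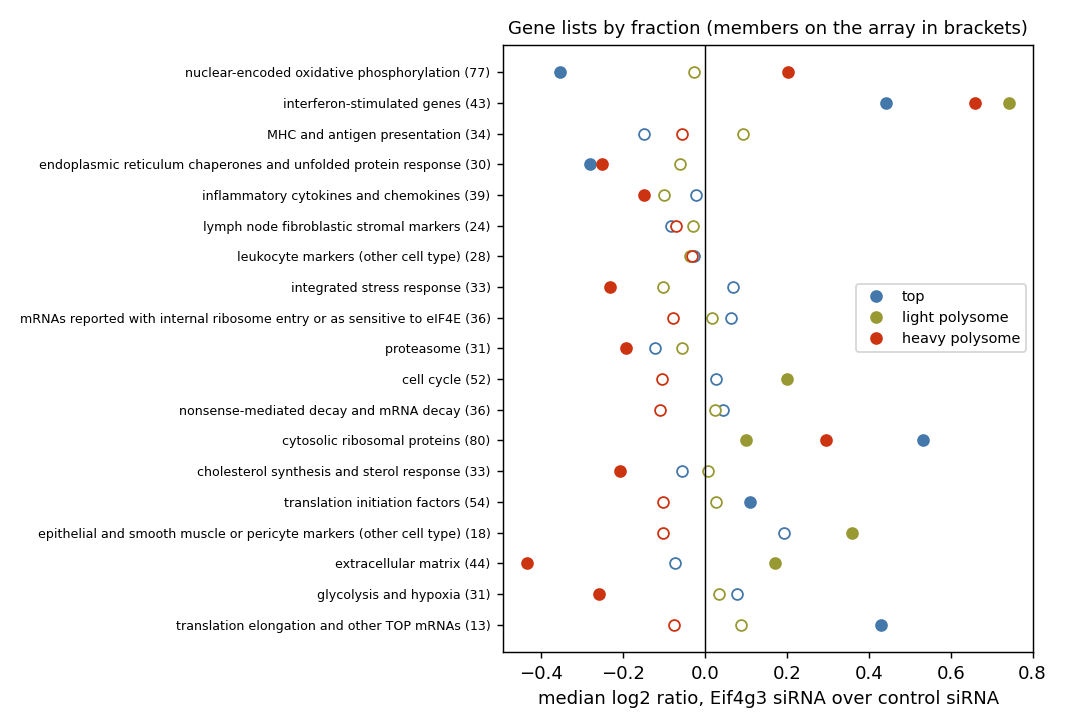
Median log2 ratio of Eif4g3 siRNA over control siRNA (x axis) of each gene list with at least 5 measured members (y axis) in the top, light and heavy fractions, ordered by heavy minus top. Filled points lie outside the range of 95% of random lists, and oxidative phosphorylation runs from -0.35 in the top to 0.20 in the heavy fraction.

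**Figure D3:**
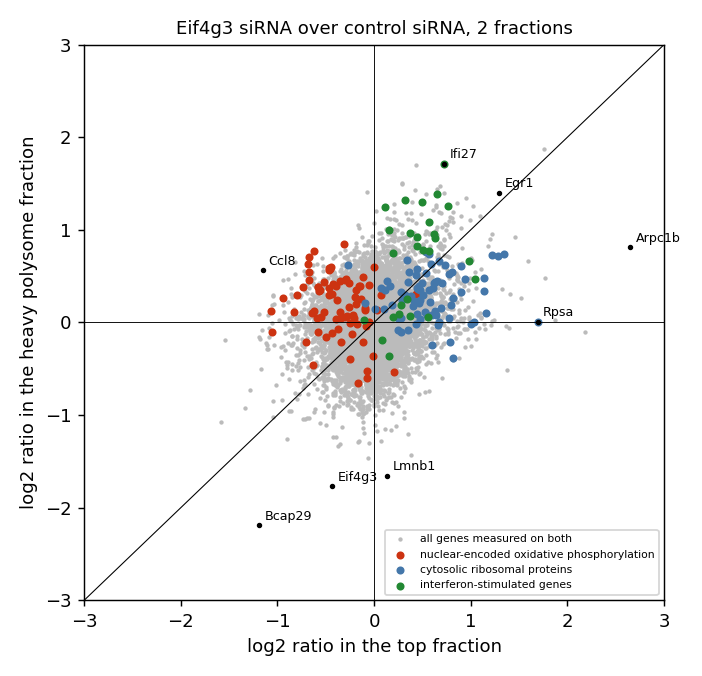
Log2 ratio of each gene in the top (x axis) against the heavy fraction (y axis), with 3 lists in colour, 8 labelled genes and the line of equal ratios. Oxidative phosphorylation genes sit mostly left of the line and ribosomal protein genes mostly right of it, with 69 of 77 and 18 of 80 having a higher ratio in heavy than in top.

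In control cells, matrix and glycolysis mRNAs had the most signal in the heavy relative to the top fraction among the gene lists. The median log2 control signal of heavy over top, which is relative to each array's signal distribution, was 1.43 for matrix, 1.15 for glycolysis and hypoxia, 1.12 for epithelial, smooth muscle and pericyte markers (7 genes), 1.02 for antigen presentation, 0.97 for proteasome, 0.90 for cell cycle and 0.52 for sterol genes. Each was above the range of random lists. Ribosomal protein genes (-0.06), oxidative phosphorylation genes (0.17) and interferon-stimulated genes (-0.56) were within it. The noncoding Rmrp was at -6.66. Over 10721 genes, 1656 were at least 2-fold higher in heavy and 2203 at least 2-fold higher in top. Across these genes the control value had Pearson's r = -0.21 (rho -0.23) with the heavy minus top difference. Both are coupled, since the control value is subtracted in that difference. Random lists were matched on mean signal and not on the control value. How far the heavy minus top shifts of lists follow the control position was therefore not tested.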

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

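The test of signal level was chosen after the list medians were seen, and the other tests were written before their results. Oxidative phosphorylation genes had opposite medians in the top (-0.35) and heavy (0.20) fractions, with a median difference of 0.55 between each gene's means on the arrays, or 0.54 over the probes measured on both, which was not tested against replicates. With an offset of 0 the heavy minus top median was 0.60, which decides nothing, since the offset pulls ratios towards 0 and so narrows a gap between medians of opposite sign. More fragmented RNA in one pool would lower probes far from the 3' end. The test used the heavy minus top difference, in which a drop shared by both fractions of a pool would largely cancel. The median 5' minus 3' probe difference over 2682 genes was -0.017 (95% bootstrap interval -0.034 to 0.0013), within the bound of 0.27. For the 19 genes of the list with such probes it was 0.077. Distance between probes was taken on the genome, introns included (median 2167 bases), so their distance on the mRNA is not known. These values show no general drop of that size in heavy minus top towards the 5' end but do not exclude fragmentation. Of random lists matched on mean signal, 0% reached the median, and 95% of them lay between -0.033 and 0.243. This is the same comparison that put the list above all random lists, so it is no separate test of signal level. It shows that lists of like mean signal did not share the shift. Signal on the top or heavy array alone was not matched, so a cause tied to it stays open. Fragmentation and the array itself stay open, the latter because it cannot be told apart from the fraction with 1 array each. Length of the mRNA also stays open, and was not tested because transcript lengths are not given in the sources used here. A change in polysome loading after Eif4g3 siRNA may be involved but was not tested further.

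Ribosomal protein genes had a median of 0.53 in the top fraction. A dye trend at the bright end could raise such bright probes together, but 0% of random lists matched on the top array's own signal reached this median. Matching was in 20 bins of signal, so a trend among the brightest probes within a bin was not tested and stays open. For lists matched on mean signal, the range of 95% was -0.153 to 0.076 on the top array. On the heavy array it was 0.033 to 0.215, which lies above 0. With an offset of 0 the median was 0.44, which decides nothing, since 0 of the 383 genes with so high a ratio on the top array fell below 0.5 times their value. The list's median was also above the range of random lists in the light (0.10) and heavy (0.30) fractions, so a rise was not particular to the top fraction. Gene-specific dye bias, for which there was no dye swap, was not tested for this list and stays open. A difference between the pooled lysates, of which there was 1 per siRNA, stays open beside a biological one.

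For the genes past 2-fold in the heavy fraction, a gene-specific dye bias would give the same ratio on all 3 arrays. Of the 99 such genes measured on both arrays, 45 (45.5%) had software ratios that differed between top and heavy by over 2 combined spot errors, against 25.1% of all genes. The software's ratio had the same sign on both arrays for 86 of the 99, against 56.6% of all 10731 genes, and both a dye bias and an siRNA effect shared by the fractions would raise that share. The test does not decide, since spot error leaves out the spread between arrays, as 25.1% of all genes show, and since genes picked on the heavy ratio have a top ratio nearer to 0 by that choice. Dye bias and an effect of the siRNA thus cannot be told apart for these genes without a dye swap.

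Extracellular matrix genes also had opposite medians, 0.17 in the light and -0.43 in the heavy fraction, with a median heavy minus light difference per gene of -0.48 that was not tested. Spop, chosen after its values were seen, was 1.04 in the top and -1.01 in the light fraction, a difference of -2.05 from 1 probe that was not tested either. The 10 spike-in probes, which entered no comparison, gave a signal above background on each array. The log2 of mRNA over spike-in signal, siRNA minus control, was -0.43 in the top, 0.22 in the light and -0.41 in the heavy fraction. From top to heavy this signal rose 15.5-fold in the control and 15.8-fold in the siRNA channel, from top to light 8.31-fold and 13.1-fold, and the amounts of spike-in added are not given in the sources used here.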

How the results depend on the processing

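The alternatives were planned before the data were examined, apart from centring on all probes and leaving the tRNA synthetase genes out of the stress response list. Leaving out a replicate was not possible with 1 array per fraction. No paired analysis was possible because each fraction has 1 array. Of 632 alternative values of list medians, 576 kept their side of the range of random lists, and of 3920 alternative values of named genes 3517 moved by less than the spot error and 0 called values changed sign. The deposited value table gave the same numbers as the software's ratio. Both count separately in these totals and in the counts of alternatives given above, but stand once below. Except where a cause is named, the cause was not tested. Signal over background limits the top array most, where 34.8% of probes were measured.

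Counts of genes higher and lower at 2-fold were 47 and 29 in the top, 56 and 41 in the light and 73 and 44 in the heavy fraction, and 87 and 75 for heavy minus top. With an offset of 0, which compresses dim ratios less by construction, they were 109 and 82, 94 and 100, 151 and 74, and 201 and 136. With the software's ratio they were 151 and 146, 148 and 156, 252 and 103, and 301 and 155, of which 25 of the 47 higher top genes and 49 of the 75 lower heavy minus top genes were shared. At 1.5-fold, a looser threshold by construction, they were 302 and 276, 490 and 371, 507 and 535, and 790 and 646. With median centring and no loess, 153 were higher in light, 202 higher and 124 lower in heavy, and 172 lower for heavy minus top. Heavy minus light gave 14 higher in place of 87, of which 1 was among the 87. Light minus top gave 34, of which 17 were among the 87, so few of the 87 were called without the top array. Of the control heavy over top counts, 1656 and 2203, bright probes alone gave 952 and 1156 with fewer genes tested, and 1.5-fold gave 2822 and 3486. Other alternatives stayed within 1.5 times. Centring on all probes, chosen after seeing the data, put the median of measured genes at 0.03 in the top, 0.62 in the light and -0.73 in the heavy fraction.

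Eif4g3 was -0.73 in the top fraction with an offset of 0 and -0.80 with the software's ratio, against -0.43, and its heavy minus top difference was -1.05 and -0.99, against -1.34. Without loess it was -0.89 in the light and -1.98 in the heavy fraction. The correlation of heavy and top, 0.24, was 0.26 with an offset of 0, 0.28 with the software's ratio, 0.21 without the background filter and 0.26 with the brightest probe. That of light and top, 0.37, was 0.23 without loess, 0.33 without the filter and 0.40 with bright probes. That of heavy and light, 0.45, was -0.062 without loess, 0.42 without the filter and 0.46 with the brightest probe.

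For heavy minus top, the interferon-stimulated median of 0.28 reversed to -0.20 with the software's ratio, and was -0.15 with an offset of 0 and -0.20 with bright probes. Stress response genes were within the range of random lists with an offset of 0 (-0.12), no loess (-0.29) and no filter (-0.14). They were also within it without their tRNA synthetase genes (0.010), chosen after seeing the data, which left their heavy fraction median below it (-0.145). Internal entry or eIF4E-sensitive genes were within it with no loess (-0.13), no filter (-0.085), bright probes (-0.13) and the brightest probe (-0.16). Cell cycle genes were within it with no filter (-0.086). Proteasome genes were within it with no background correction (-0.12), the software's ratio (-0.093) and no loess (-0.24). mRNA decay genes were within it with no background correction (-0.15), an offset of 0 (-0.16), no filter (-0.13) and bright probes (-0.20).

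In the top fraction, interferon-stimulated genes were within the range with bright probes (0.24). Lists that left it were stromal markers with no background correction (-0.14), glycolysis genes with the software's ratio (0.17), mRNA decay genes with bright probes (0.27), and epithelial, smooth muscle and pericyte markers with the software's ratio (0.35) and no filter (0.079). In the light fraction the last list was within it with no loess (0.019) and no filter (0.051). Lists that left it there were antigen presentation with no loess (0.29), cytokines with no background correction (-0.14) and the brightest probe (-0.13), stress response with the software's ratio (-0.18), no loess (-0.068), bright probes (-0.17) and the brightest probe (-0.16), and endothelial markers with the software's ratio (-0.47) and no loess (-0.59). In the heavy fraction cytokines were within it with no background correction (-0.087), the software's ratio (-0.083), no loess (-0.12), no filter (-0.013) and bright probes (-0.085). Lists that left it were initiation factors with an offset of 0 (-0.11), the software's ratio (-0.11) and the brightest probe (-0.086), eIF4E-sensitive genes with bright probes (-0.22), and cell cycle genes with the software's ratio (-0.13), no loess (-0.24) and the brightest probe (-0.13).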

Other observations

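Several gene families, chosen by name after the named genes were seen, differed between the fractions. Histone genes had a median heavy minus top difference of 0.70, with 37 of 39 above 0, from -0.18 in the top to 0.44 in the heavy fraction. Spliceosomal Sm and Lsm genes, 1 of which is in the mRNA decay list, had 0.43 (20 of 26 above 0), mitochondrial import genes 0.34 (14 of 18) and mitochondrial ribosomal protein genes 0.29 (58 of 74, 6 past 2-fold). Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, had -0.30 (5 of 29 above 0), and the 23 measured ones outside the stress response list -0.21 (percentile 1.54), which was within the range of random lists with an offset of 0 (-0.11, percentile 14.3) and without loess (-0.30, percentile 4.24). Tubulin genes had -0.33 (3 of 14 above 0), with medians of 0.30 in the top and 0.43 in the light fraction. The directions of heavy minus top of these 6 families were the same with no background correction, an offset of 0, the software's ratio and no loess, but mitochondrial ribosomal protein genes had 0.14 without loess (48 of 74 above 0) and 0.44 with the software's ratio, and mitochondrial import genes 0.21 without loess. Histone and Sm mRNAs are short, and whether these differences follow mRNA length in place of family was not tested, since transcript lengths are not given in the sources used here.

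The vacuolar ATPase genes had -0.25 in the heavy fraction over 19 measured genes, and a heavy minus top difference of 0.00. The Arp2/3 complex, 2 of whose genes, Arpc1a and Arpc1b, were past 2-fold in the top fraction, had a median of -0.21 there over 7 measured genes, so its other members did not share their direction. Non-muscle myosin genes had 0.29 in the light fraction over 6 measured genes.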
